A study of Mus musculus with 2 samples.

How the data were processed

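The data are long-read RNA sequencing libraries of the gastrocnemius muscle of 2 female mice, 1 library each. The labels call them biological replicates 1 and 2 of 1 group, number the animals 3 and 4, name 2 biosamples and give both the same donor record, so spread between the libraries holds animal, dissection and library differences together. The deposited tables hold counts per transcript model with no normalization, as their whole-number values show. The notes deposited with them name the mm10 assembly and the GENCODE M21 annotation, and the deposited gene models name TALON as their source. The sequencing platform, the aligner, the versions and any read filter are not given in the sources used here. Each table lists models with 1 or more counts and gives exon numbers and lengths in bases. These were checked against the deposited gene models and were equal for all 75228 models of replicate 1 and 94598 of replicate 2, spike-ins included. Models of the libraries were matched by chromosome, strand and intron chain. The labels name spike-in mixes: ERCC sequences were present and were left out of totals, and the second mix was not analysed here.

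Gene counts were sums over models, and CPM used all reads without spike-ins. Values per group are means ± SD over n = 2. Log2 ratios are replicate 2 over replicate 1 with 0.5 reads added to each count. With 1 group no test between groups exists. Fisher's exact test, two-sided, compared each gene's reads with the rest of the library for genes with 10 or more reads over both, with Benjamini-Hochberg adjustment. Isoform shares were compared for chains that were annotated, NIC or NNC in either library, with 5 or more reads over both and 20 or more such reads per gene in each library, by Fisher's exact test for 2 isoforms and otherwise a chi-square statistic with 100000 Monte Carlo permutations where 2000 gave a p of 0.02 or less. Gene lists were placed among 10000 random lists, each member drawn from its 100 nearest genes in mean expression. Dispersion came from edgeR 4.0.16 with an intercept alone, and size factors from DESeq2 1.42.0, in R 4.3.3. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6.

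Tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule took the 20 genes with the highest mean CPM, the most read 4 members of each list, up to 15 genes of a fixed isoform list, the 10 most read chains outside the annotation, the 5 largest ratios each way, 5 genes with differing isoform shares and 5 unannotated genes. Cyr61, Dmrtc1 and Lncmyh are not in the annotation under these names and were not measured. Results for a few genes the rule took are not reported. Ankrd2, Casq2, Myh3, Myh8, Pkm, Cdkn1c, Col1a2 and other list members outside the leading 4 were named after their values were seen, unless another part of the rule took them. Alternatives changed the scaling, count minimums, transcript classes and thresholds and left out each replicate. Alternatives added after seeing the data were a class definition from annotated splice sites alone, removal of the length trend (lowess with a fraction of 0.4 on log2 length, then an exact binomial test), random lists matched on length, leaving out Atp2a1, an exact binomial test or edgeR's exact test at a dispersion of 0.0001 in place of Fisher's, the ISM share against the length of the most read model or with that class definition, and the class taken per library in the isoform test. Gene length was at first that of the most read annotated transcript. That definition gave Atp2a1 a length its reads do not have, so it was replaced after seeing the data by the length of the most read annotated, NIC or NNC model, which differed for 653 of 8423 genes. Both definitions are reported.

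The gene, isoform, list and dispersion steps were tested on simulated data. With 200 of 8892 genes changed by 2-fold, Fisher's test recovered 34.0% of them with 3 false calls, and at 4-fold 64.0% with 5 false calls. These false calls hold for the simulated noise and give no error rate for the libraries, whose coefficient of variation was estimated at 0.327. With leading isoform shares of 200 of 1677 genes moved by 30 percentage points, 79.0% were recovered with 6 false calls. With no difference simulated, 6 of 86 lists fell outside the central 95% of random lists. Dispersion estimates were low: a simulated coefficient of variation of 0.3 gave 0.283 and one of 0.6 gave 0.505. Reads carry no molecular identifiers in the tables, so intervals treat reads as independent molecules.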

Results

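Long-read RNA sequencing libraries were compared from the gastrocnemius, a mostly fast-twitch calf muscle, of female B6CASTF1/J mice aged 25 days, a first-generation cross of C57BL/6J with the wild-derived CAST strain. The labels give 1 group with 2 biological replicates, each made from 2 µg of total RNA, so there is no contrast between conditions: the text describes the transcripts of this muscle and how far the 2 libraries differed. Replicate 1 held 1100764 reads and replicate 2 held 1588661. ERCC spike-in RNAs took 30993 of these in replicate 1 and 31067 in replicate 2, which left 1069771 and 1557594 reads from the mouse. A gene with 0 reads could stand at up to 2.80 CPM (counts scaled to library size) in replicate 1 and 1.93 CPM in replicate 2. Intervals are exact Clopper-Pearson 95% intervals, and they and these floors cover counting error only.

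Calcium pump, actin and creatine kinase transcripts led the muscle's reads. Atp2a1 (ENSMUSG00000030730.12, chromosome 7, 126445858 to 126463108, minus strand, mm10), the calcium pump of fast sarcoplasmic reticulum, averaged 107167 ± 71782 CPM (SD, n = 2), with 157925 CPM in replicate 1 and 56409 CPM in replicate 2. Skeletal actin Acta1 (ENSMUSG00000031972.5, chromosome 8, 123891769 to 123894751) was at 74630 ± 902 CPM, and the muscle creatine kinase Ckm (ENSMUSG00000030399.2, chromosome 7, 19404776 to 19422841) at 64789 ± 6882 CPM. The fast troponin C gene Tnnc2 stood at 26991 ± 11860 CPM, the tropomyosin gene Tpm1 at 20020 ± 4979 CPM, and the myosin light chain genes Mylpf and Myl1 at 17975 ± 6212 and 15683 ± 6462 CPM. Next came Aldoa, Slc25a4, Myh4, Eno3, Ldha, Tcap, Actn3, Casq1, Ak1, Atp5b, Tpm2, Myh1 and Mybpc2. These 20 genes together took 45.7% of reads in replicate 1 and 39.6% in replicate 2. Reads were seen for 12022 annotated genes in both libraries, 11034 of them protein-coding, and for 15521 in either. Of the 3499 genes seen in 1 library alone, 2249 had a single read.

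Myh4, which encodes the fast IIB myosin heavy chain, held 69.3% ± 6.83 (SD, n = 2) of the reads from the 10 sarcomeric myosin heavy chain genes. Its share was 64.4% (63.9 to 65.0) of 27167 reads in replicate 1 and 74.1% (73.4 to 74.7) of 16743 reads in replicate 2. Myh1, the IIX gene, held 30.2% (29.7 to 30.8) and 14.0% (13.5 to 14.5), and Myh2, the IIA gene, 3.96% (3.74 to 4.2) and 5.59% (5.25 to 5.95). The slow gene Myh7 held 1.34% (1.21 to 1.49) in replicate 1 and 6.19% (5.83 to 6.56) in replicate 2. Embryonic Myh3 had 11 and 13 reads and neonatal Myh8 had 1 and 5. No read came from Myh15, which allows a share of up to 0.0110% in replicate 1 and 0.0179% in replicate 2. Over reads matching annotated transcripts alone the mean Myh4 share was 42.4%, and a 40-exon Myh4 chain outside the annotation took 5153 reads in replicate 1 and 1595 in replicate 2, 29.4% and 12.9% of the gene. Several of these genes are close paralogs, and how ambiguous reads were assigned is not given in the sources used here.

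**Figure D1:**
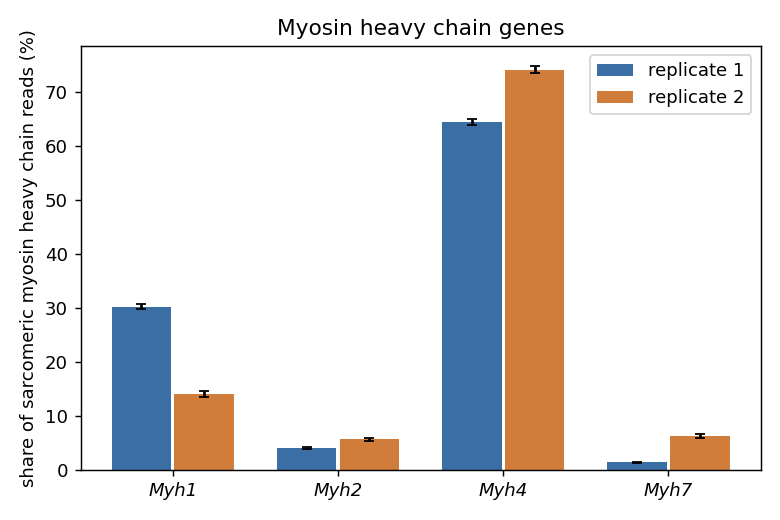
Share of sarcomeric myosin heavy chain reads (%, y axis) from 4 genes (x axis) in each library, with bars for the share and error bars for the exact 95% interval. Myh4 led in both libraries, at 64.4% and 74.1%, and for each of the 4 genes the intervals of the libraries did not overlap.

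Contractile, energy-buffering and respiratory chain genes made up the largest measured lists, followed by glycolytic genes. The 15 fast-fibre contractile and calcium genes took 23.1% ± 5.53 of reads (SD, n = 2). The 29 thin filament, thick filament and Z-disc genes common to all fibres took 10.5% ± 0.0967, led by Acta1, Tcap, Tpm2 and Des. Glycolysis and glycogen breakdown genes took 4.74% ± 0.130, led by Aldoa at 12984 ± 221 CPM and Eno3 at 9705 ± 495 CPM. Gapdh, also in this list, had 61 reads in replicate 1 and 80 in replicate 2. Whether reads of it were placed elsewhere was not tested, so the list total may be low. Creatine and adenylate buffering genes, led by Ckm, Slc25a4 and Ak1, took 8.60% ± 0.979. The 95 nuclear genes of the respiratory chain and ATP synthase took 6.48% ± 2.49, with Atp5b at 4741 ± 1492 CPM and Cox4i1 at 3921 ± 1975 CPM. Excitation-contraction coupling genes took 1.06% ± 0.00958, led by Srl, Hrc and Trdn. Cytosolic ribosomal protein genes took 1.37% ± 0.659. Dystrophin complex genes were at 961 ± 141 CPM, proteolysis and atrophy regulators at 1744 ± 159 CPM and myogenic factors at 485 ± 136 CPM, with Mef2c and Mef2d the most read of the last list. Imprinted genes were at 2209 ± 41.8 CPM, led by Gnas at 1020 ± 2.46 CPM and H19 at 749 ± 6.16 CPM. The circadian clock genes were at 590 ± 89.8 CPM, led by Dbp and Tef, and the immediate early and heat shock genes at 210 ± 66.5 CPM, led by Nr4a1.

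Transcripts of other cell types in the muscle were measured beside these. Fibroblast genes were at 5845 ± 1420 CPM, led by Col3a1 at 1685 ± 1386 CPM and Gsn at 1345 ± 283 CPM. Endothelial genes were at 551 ± 81.7 CPM, Schwann cell and nerve genes at 229 ± 84.4 CPM, neuromuscular junction genes at 228 ± 109 CPM and macrophage and other leukocyte genes at 139 ± 27.5 CPM. The smooth muscle and pericyte list was at 3809 ± 13.3 CPM, of which Des, also a skeletal muscle gene, gave 3528 ± 112 CPM. The adipocyte list was at 3649 ± 1930 CPM, of which Car3, also a slow muscle gene, gave 3281 ± 2232 CPM. Blood genes were at 949 ± 553 CPM, led by Hba-a1 at 419 ± 276 CPM, whose reads can be shared with its near-identical copy Hba-a2. The embryonic and neonatal muscle list was at 1006 ± 148 CPM, most of it from H19, while Chrng, Mybpc3 and Tnnt2 had 0 reads in both libraries. Cartilage and bone genes were at 12.6 ± 6.0 CPM and keratinocyte genes at 10.6 ± 3.13 CPM. Keratinocyte reads were almost all from Krt10. The 6 Y-linked genes had 0 reads, which allows up to 2.80 and 1.93 CPM.

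Slow-fibre and tendon genes set the libraries furthest apart among the fixed lists. Of the 13 slow-fibre genes with 10 or more reads, 10 were higher and 2 lower in replicate 2, and 1 did not pass; 12 passed when adjusted over the list alone. Tnnt1, the slow troponin T gene, had 204 reads in replicate 1 and 5366 in replicate 2 (log2 ratio 4.17), Tpm3 189 and 2048 (2.89) and Tnnc1 129 and 1878 (3.32), while Csrp3 (-0.78) and Ankrd2 (-0.75) were lower. Of 9 tendon genes, 8 were higher in replicate 2 and 1 did not pass, also 8 when adjusted over the list alone, with Fmod at 22 and 259 reads and Chad at 5 and 103. Casq2 was the slow-fibre gene that did not pass, with 88 and 102 reads. The median log2 ratio, replicate 2 over replicate 1, was 2.89 for the slow list and 2.14 for the tendon list, each at percentile 100 among 10000 random lists matched on expression. These are Fisher's exact tests on the reads of 2 libraries with Benjamini-Hochberg adjustment, and they compare those libraries, not conditions.

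Mitochondrially encoded protein genes, at 0.341% ± 0.234 of reads (SD, n = 2), were also higher in replicate 2: all 9 measured members passed, and 9 when adjusted over the list alone, led by mt-Cytb (463 and 3083 reads, log2 ratio 2.19) and mt-Co1 (804 and 2442 reads, 1.06). Of 91 nuclear respiratory chain genes 72 were higher, 3 lower and 16 did not pass, with 80 passing when adjusted over the list alone. Of 84 ribosomal protein genes 71 were higher, 0 were lower and 13 did not pass, with 75 passing when adjusted over the list alone. Transcript length moved with these groups: across 6763 genes, which are not independent replicates, the Spearman correlation of the log2 ratio with transcript length was -0.55. The median log2 ratio was 1.03 for 147 genes of up to 500 bases and -0.63 for 748 genes above 5000 bases. With the length trend removed, an alternative chosen after seeing the data, the median was 0.19 for the respiratory chain list, 0.23 for the ribosomal list, 0.90 for the mitochondrially encoded list, 2.40 for the slow list and 2.52 for the tendon list, and 42 respiratory chain, 18 ribosomal, 9 mitochondrially encoded, 10 slow-fibre and 8 tendon genes passed upward, against 1, 0, 0, 2 and 0 downward.

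**Figure D2:**
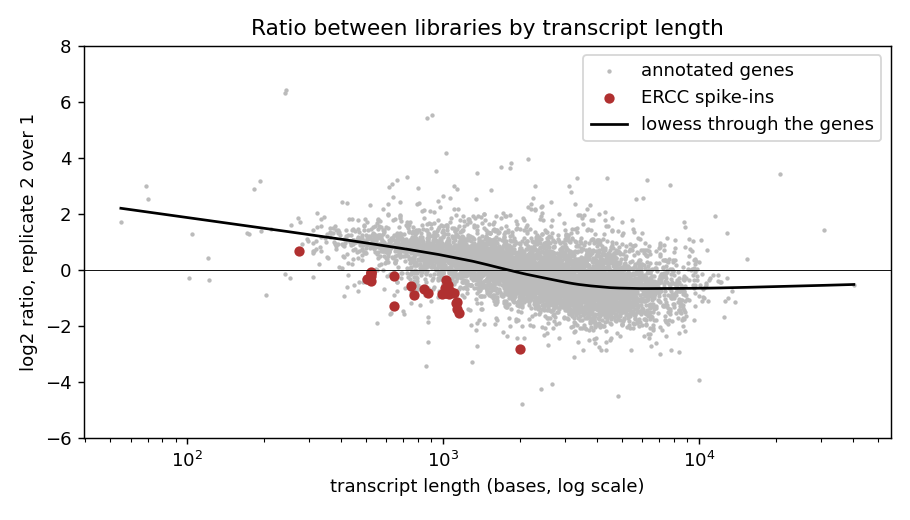
Log2 ratio (y axis, replicate 2 over replicate 1) of each annotated gene (grey points) and ERCC spike-in (red points) by transcript length (x axis, bases, log scale), with a lowess line through the genes. The median of the genes falls from 1.03 for genes of up to 500 bases to -0.63 for genes above 5000 bases.

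Blood, adipocyte, nerve and synaptic genes were lower in replicate 2. Of 6 blood genes, 5 were lower and 1 higher (6 adjusted over the list alone), with Hbb-bs at 374 and 188 reads. Of 11 adipocyte genes, 8 were lower, 1 higher and 2 did not pass (9 adjusted over the list alone): the adipsin gene Cfd had 290 and 116 reads and the desaturase gene Scd1 69 and 4, while Car3 was higher (log2 ratio 1.51). Of 11 neuromuscular junction genes 7 were lower and 4 did not pass (7 adjusted over the list alone), with Ache at 63 and 23 reads. Of 5 Schwann cell and nerve genes 4 were lower and 1 did not pass (5 adjusted over the list alone), with Mbp at 93 and 40 reads. Median log2 ratios were -1.56, -1.86, -1.02 and -1.38 for these lists, at percentiles 0, 0, 0.595 and 0.295 of matched random lists. With the length trend removed 5 blood, 6 adipocyte, 3 neuromuscular junction and 3 Schwann cell genes passed downward, and 1, 1, 0 and 0 upward. Of 27 lists with 5 or more measured members, 8 lay above and 8 below the central 95% of random lists. Matched on length as well, over members with a length and chosen after seeing the data, 5 lay above and 7 below.

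Fast-fibre genes went both ways. Of 15 measured, 7 were higher and 8 lower in replicate 2 (15 adjusted over the list alone), with Tnnc2 (log2 ratio 0.93) and Myl1 (0.87) higher and Atp2a1 (-1.49) and Myh1 (-2.35) lower. The fast-fibre median was -0.36, at percentile 1.45 of random lists matched on expression and 2 when also matched on length. With the length trend removed it was -0.09. Of 5 measured myosin heavy chain genes 1 was higher, 3 lower and 1 did not pass (4 adjusted over the list alone). Of 29 filament and Z-disc genes 6 were higher, 16 lower and 7 did not pass (23 adjusted over the list alone), with Tcap higher (0.59) and Mybpc1 lower (2908 and 1348 reads, -1.65). Among 19 glycolytic genes 4 were higher, 9 lower and 6 did not pass (14 adjusted over the list alone), with Pkm lower (-0.59). Among 8 buffering genes 3 were higher, 3 lower and 2 did not pass (7 adjusted over the list alone), with Slc25a4 higher (0.61). Among 21 excitation-contraction coupling genes 5 were higher, 7 lower and 9 did not pass (12 adjusted over the list alone). With the length trend removed, those past the test upward and downward were 5 and 7 fast-fibre, 1 and 2 myosin, 4 and 13 filament, 4 and 6 glycolytic, 2 and 2 buffering and 3 and 3 coupling genes. Tcap (0.03) then no longer passed, Tnnc2 (0.16) and Myl1 (0.19) kept little of their ratio, and Mybpc1 (-1.07) stayed lower.

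None of 15 dystrophin complex genes was higher, 5 were lower and 10 did not pass (5 adjusted over the list alone). Proteolysis regulators had 4 higher, 4 lower and 6 that did not pass (8 adjusted over the list alone). Myogenic factors had 0 higher, 4 lower, Mef2c and Mef2d among them, and 7 that did not pass (4 adjusted over the list alone). Embryonic and neonatal genes had 3 higher, 0 lower and 4 that did not pass (3 adjusted over the list alone), with Actc1 at 128 and 428 reads. Imprinted genes had 1 higher (Igf2, 3 and 28 reads), 1 lower (Cdkn1c) and 12 that did not pass (2 adjusted over the list alone). Fibroblast genes had 3 higher, 6 lower and 8 that did not pass (10 adjusted over the list alone), endothelial genes 1, 5 and 9 (8), and smooth muscle genes 0, 5 and 5 (5). Leukocyte genes had 1 higher (Lyz2) and 8 that did not pass (0 adjusted over the list alone). Immediate early and heat shock genes had 2 lower (Jun and Hsph1) and 10 that did not pass (2 adjusted over the list alone), and circadian genes 1 lower (Tef) and 12 that did not pass (1 adjusted over the list alone). Long noncoding RNAs had 3 higher and 6 that did not pass (4 adjusted over the list alone), and both mitochondrial rRNA genes were higher (2 adjusted over the list alone). The single measured genes of the cartilage and bone list, Alpl (1 adjusted over the list alone), and of the keratinocyte list, Krt10 (0), did not pass. With the length trend removed the balance turned for fibroblast genes, with 4 upward and 2 downward, and the counts upward and downward were 2 and 3 for dystrophin complex, 3 and 1 for proteolysis, 0 and 3 for myogenic, 3 and 0 for embryonic and 2 and 1 for imprinted genes. They were 0 and 5 for endothelial, 1 and 4 for smooth muscle, 0 and 1 for immediate early, 2 and 0 for long noncoding and 2 and 0 for mitochondrial rRNA genes, and 0 and 0 for leukocyte and circadian genes, so Lyz2 and Tef no longer passed, nor did Hsph1.

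**Figure D3:**
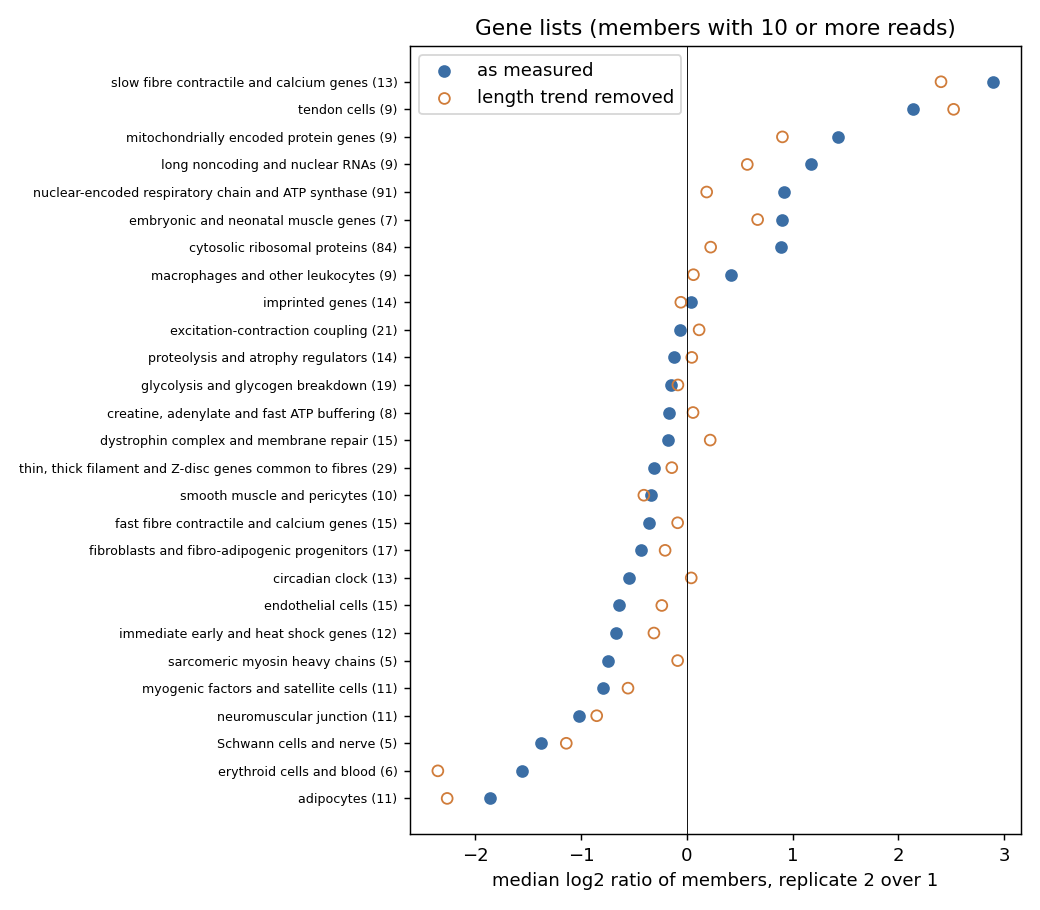
Median log2 ratio of list members with 10 or more reads (x axis, replicate 2 over replicate 1) for each gene list (y axis, members in brackets), as measured (filled) and with the length trend removed (open). The slow-fibre list had the highest median as measured, 2.89, and the adipocyte list the lowest, -1.86.

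Across all annotated genes, 2311 of 8892 with 10 or more reads differed between the 2 libraries by Fisher's exact test at an adjusted p of 0.05, 983 higher and 1328 lower in replicate 2. The share that was higher was 42.5% with total reads as the scale, 59.1% with TMM and 63.2% with DESeq2 size factors, so the split depends on the scaling. With the length trend removed, chosen after seeing the data, 1144 of 8752 genes with a length differed, 56.6% of them higher. Without removal the same exact binomial test on these genes called 2263, 41.6% of them higher. Removing the trend also takes out the overall level of the ratios, so this turn cannot be assigned to length apart from scaling. TMM raised every log2 ratio by 0.17 and DESeq2 by 0.22, and under both the direction turned for Ldha, Ak1 and Tpm2 among the 20 most read genes. Usp50 had the largest ratio, with 1 read in replicate 1 and 371 in replicate 2 (log2 ratio 7.41, 5.51 to 13.30). Gm34302 (0 and 62 reads) was at least 14.2-fold higher, Fxyd7 (0 and 57) at least 13.1-fold and Gm29253 (0 and 48) at least 11-fold, against a floor of 3 counts per library; 1500015O10Rik had 3 and 238 reads (log2 ratio 5.55, 4.2 to 8.06). In the other direction Gm6829 (38 and 0) was at least 18.4-fold and Gm15935 (30 and 0) at least 14.6-fold lower, and Alas2 (28 and 1, log2 ratio -4.79, -10.70 to -2.75), Scd1 (69 and 4) and Vcp-rs (175 and 13) followed. By the deposited classes, no read of Usp50, Gm29253, Gm6829 or Gm15935 in either library was a complete chain (annotated, NIC or NNC). Gm6829 and Vcp-rs are pseudogenes whose reads can be shared with their parent genes, and genes that overlap another gene are uncertain in the same way. Pearson's correlation of log2(CPM + 1) across 15521 genes was 0.915 and Spearman's was 0.885, across genes and not over independent replicates. The biological coefficient of variation from edgeR was 0.327 over 5903 genes. At a fixed dispersion of 0.04 edgeR's exact test called 200 genes, 105 of them higher in replicate 2. That dispersion is a coefficient of variation of 0.2, below the 0.327 estimated from the libraries.

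Transcripts matching an annotated model took 65.7% ± 2.83 of reads (SD, n = 2). By the deposited labels, NIC (a name for unannotated combinations of annotated splice sites) took 5.10% in replicate 1 and 8.26% in replicate 2, and NNC (chains with an unannotated splice site) 18.3% and 2.5%. Of the reads labelled NIC, 18.0% in replicate 1 and 71.1% in replicate 2 held a splice site outside the annotation. Incomplete matches to a model (ISM) took 8.31% and 11.7%, and genomic reads 2.19% and 5.38%. The class labels were not given alike in the libraries: of 15202 shared chains outside the annotation, 1206 had another class in the second library. With 1 definition from the annotated models, chosen after seeing the data, NIC took 4.39% and 3.57%, which turns its direction between the libraries, and NNC 19.7% and 8.66%.

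**Figure D4:**
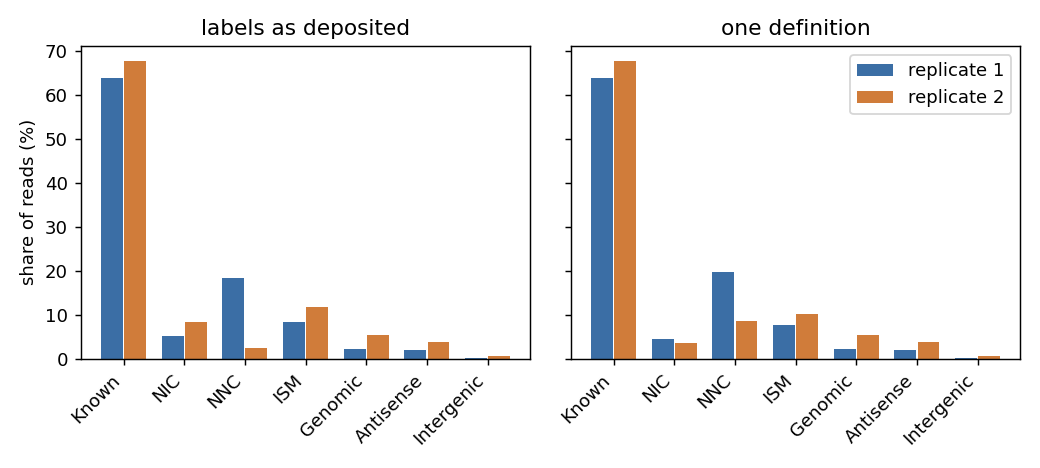
Share of reads (%, y axis) per transcript class (x axis) in each library, with the labels as deposited (left) and with 1 definition for both libraries (right). The NNC share of replicate 2 was 2.5% as deposited and 8.66% with 1 definition.

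A single Atp2a1 chain outside the annotation accounts for much of these classes. The 22-exon chain took 159339 reads in replicate 1, 94.3% of the gene and 14.9% of the library, and 80454 reads in replicate 2, 91.6% of the gene and 5.17% of the library. It was labelled NNC in replicate 1 and NIC in replicate 2. Its first intron ran from 126462188 to 126462778 on chromosome 7 (mm10), where the 23-exon annotated model has an intron from 126462188 to 126462499, an 18-base exon and an intron from 126462518 to 126462804. The annotated first intron was used by 11 reads in replicate 1 and 5 in replicate 2. Exons this short depend on the alignment, which was not analysed here. At the other end of the gene, a 42-base exon (126446545 to 126446586) was skipped in 0.313% (0.287 to 0.341) of reads in replicate 1 and 0.418% (0.376 to 0.463) in replicate 2.

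**Figure D5:**
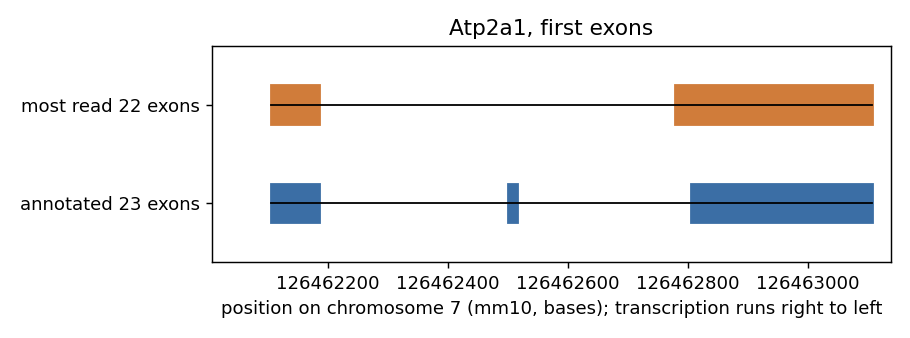
Position on chromosome 7 (mm10, bases, x axis) of the first exons of the annotated 23-exon Atp2a1 model and of the most read 22-exon chain, with boxes for exons and lines for introns. The most read chain lacks the 18-base exon and its first exon extends 26 bases further.

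Contractile and metabolic genes differed in how many isoforms they used. Among 3122 genes with 20 or more isoform reads in each library, 800 (25.6%) had 2 or more isoforms above 10% of reads in both libraries, 1132 had 2 or more above 5%, 1445 had a single isoform counted, and 3023 had the same leading isoform in both. Acta1-201 held 99.0% ± 0.0263 of its gene's isoform reads (SD, n = 2), Ckm-203 99.5% ± 0.0266, Tpm1-205 98.7% ± 0.155, Mylpf-201 99.5% ± 0.205, Tpm2-202 97.1% ± 0.168, Pkm-202 97.0% ± 0.495, Mybpc2-201 97.3% ± 0.232 and Des-201 99.4% ± 0.0538. Pgam2-201 was the only Pgam2 isoform counted in either library. Myl1, which encodes the essential light chains of fast myosin, was split between Myl1-202 at 68.9% ± 3.02 and Myl1-201 at 23.1% ± 3.54, and Eno3 between Eno3-201 at 58.3% ± 1.75 and Eno3-202 at 25.7% ± 0.733. Ndrg2-201 held 49.7% ± 0.0313, and an unannotated 16-exon chain with another first exon held 44.7% ± 0.712. Aldoa was led by an unannotated 9-exon chain at 89.0% ± 2.32.

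Isoform shares differed between the 2 libraries for 33 of 1677 genes at an adjusted p of 0.05, 17 of them by 10 percentage points or more, and 166 had an unadjusted p under 0.05 (Monte Carlo permutation or Fisher's exact test on reads of those libraries). Mybpc1, the slow myosin-binding protein C gene, used Mybpc1-202 for 1.80% (1.32 to 2.40) of reads in replicate 1 and 23.1% (20.7 to 25.7) in replicate 2. Tpm3-205 held 77.9% of Tpm3 reads in replicate 1 and 95.7% in replicate 2, while Ddx5-208 (43.0% and 15.8%), Tsc22d3-201 (65.1% and 41.7%) and Tef-201 (84.0% and 61.5%) were lower in replicate 2. For these 5 genes the Monte Carlo permutation p was 1e-05, the smallest that could be reached.

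Unannotated chains with enough reads were found in both animals. Finding a chain again does not tell a real isoform from an error of alignment or annotation. The libraries share the cross, the assembly and the annotation, so such errors can recur as well. Of chains labelled NIC in the deposit with 5 or more reads, 94.8% (93.3 to 96.1) of those in replicate 1 were found in replicate 2, and 96.1% (94.7 to 97.1) in the other direction. For chains labelled NNC the shares were 96.3% (94.6 to 97.7) and 91.1% (89.0 to 93.0), against 98.7% and 98.6% for annotated chains. These pool chains of all depths: with 1 class definition, chains of replicate 1 with 5 to 9 reads were found in replicate 2 for 96.2% (95.4 to 97.0) of annotated, 90.9% (88.0 to 93.3) of NIC and 91.0% (88.3 to 93.3) of NNC chains, and those with 10 to 19 reads for 99.5% (99.0 to 99.8), 99.5% (97.4 to 99.99) and 99.6% (97.7 to 99.99). The most read of the 587 such chains with 10 or more reads in both libraries, after Atp2a1, Aldoa and the Myh4 chain, were in Tnni2 (1941 and 4085 reads), Oaz1 (1184 and 2764), Srl (2496 and 1269), Ndrg2 (1018 and 1085), Vdac3 (556 and 895), Idh3b (394 and 864) and Acta1 (456 and 649). The Oaz1 chain differs from Oaz1-201 by lacking an annotated intron of 4 bases, from 80828292 to 80828295 on chromosome 10. The Vdac3 chain differs from Vdac3-202 by an intron end at 22587548 in place of 22587549 on chromosome 8.

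Incomplete reads took a larger share of the typical long gene than of the typical short gene. Across genes, which are not independent replicates, the Spearman correlation of a gene's ISM share with the length of its most read annotated transcript was 0.35 over 4039 genes in replicate 1 and 0.30 over 4246 genes in replicate 2. The median gene of up to 500 bases had an ISM share of 0.812% in replicate 1 and 0.820% in replicate 2, and the median gene above 5000 bases 11.5% and 12.1%. Shares over all reads of a length class rest on a few genes: above 5000 bases they were 28.7% and 41.2%, and 24.1% and 26.7% without Myh4. Up to 500 bases they were 13.5% and 11.6%, above those of most longer classes in replicate 1. From 1500 to 2000 bases they were 5.53% and 17.7%, and 5.37% and 8.12% without Aldoa, whose most read chain was labelled NIC in replicate 1 and ISM in replicate 2. Atp2a1 stood among genes of 500 to 1000 bases by its annotated transcript, though its most read chain has 3485 bases.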

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

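The tests of explanations in this part were chosen only after the result they bear on was seen. Signal outside the main comparisons was found in both libraries, above the 3 reads that a count of 0 allows. Spike-in sequences held 30993 reads in replicate 1 and 31067 in replicate 2. Genes antisense to annotated genes held 22984 and 61500 reads, and genes between annotated genes 3126 and 11254. Of the 8319 such loci in replicate 1, 3086 (37.1%) overlapped a locus of replicate 2 by 50% or more of each, and of the 19551 in replicate 2, 3088 (15.8%) overlapped one of replicate 1. The most read shared locus lay opposite Gm26917 on chromosome 17 (39843013 to 39846245, minus strand), with 4993 and 1281 reads. Others lay opposite 2900097C17Rik (134 and 625 reads), at an intergenic site on chromosome 7 from 28187294 (306 and 427), and opposite Pitpnc1 (241 and 380).

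The ratio between the libraries fell with transcript length: the 15 spike-ins of 900 to 1300 bases had a median log2 ratio 0.60 below that of the 9 spike-ins under 700 bases (difference -0.60, exact permutation p = 0.00197), and the gene medians at like lengths differed by -0.41. Breakage of the RNA before spike-ins were added leaves spike-ins untouched, so the spike-in correlation with length of -0.76 over 29 spike-ins (permutation p = 1e-05, the smallest 100000 permutations can give) argues against it as the whole cause, if spike-ins went in after extraction, a step not given in the sources used here. A length-dependent yield of library preparation or sequencing is consistent with the shift of -0.60. Above 1300 bases there was 1 spike-in, so added breakage of longer RNA stays open, and no biological explanation was tested.

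Slow-fibre genes were higher in replicate 2. Transcript length as the whole cause is argued against by the median log2 ratio of 2.40 that the list kept with the length trend removed, with 10 of 13 genes past the threshold upward and 2 downward (the median was 1.65 with annotated transcript lengths). Heart RNA is argued against by 6 heart genes, 3 of them also in the myosin or embryonic lists, which had 3 reads in replicate 1 and 4 in replicate 2, all from Myh6: at 2.57 CPM they reach 0.793% of the Myh7 excess of 324 CPM. More slow muscle in the piece sampled may account for the 10 genes that were higher, but Csrp3 and Ankrd2, also slow-fibre genes, were lower. Mybpc1, named for slow myosin-binding protein C, was lower too (2908 and 1348 reads, log2 ratio -1.65, and -1.07 with the length trend removed). The fixed lists held Mybpc1 among genes common to all fibres, so it is not one of the 13 slow-fibre genes counted. That placement was not tested here. With 1 library per animal, more slow muscle and a difference between the animals cannot be told apart.

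The same intron chain carried different classes in the libraries. In replicate 2, 71.1% of reads labelled NIC hold a splice site outside the annotation (18.0% in replicate 1), mostly 1 Atp2a1 chain of 80454 reads, and without Atp2a1 the share is 21.2% (16.2% in replicate 1); in both, 0 reads labelled NNC had annotated sites alone. This is consistent with splice sites met in earlier reads being counted as known, a hypothesis formed on the same data. Of 1224 chains with 10 or more reads in both libraries, 8.01% (6.55 to 9.67) still differed in class. This argues against few reads per chain as the whole cause. Of 13978 chains with fewer reads, 7.93% (7.48 to 8.39) differed, so whether few reads played a part among those stays open. No biological explanation was tested.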

How the results depend on the processing

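Tests with removed length trend by either length, length-matched lists, Atp2a1 left out, ISM share against the other length, classes from annotated models, classes per library or another test alone were chosen only after the result was seen. Of the alternatives of planned results, 304 gave a list median with the same direction and side of the threshold, a count or coefficient of variation within 1.5 times, a correlation within 0.05, or a share or CPM within 1 SD of 2 libraries. For lists and classes whose libraries differ that SD is wide, so the myosin list at 11126 CPM with complete chains (18072 in all reads), intergenic reads at 0.280% among transcripts with 5 or more reads (0.484% in all) and NNC at 14.2% with 1 class definition (10.4% as deposited) are among them. So are all 78 that leave out a replicate, by construction except for detected genes. Without replicate 1, values over 1.5 times from the mean were NNC 2.5% and the lists for myosin 10749, slow-fibre 9231, mitochondrial rRNA 172, neuromuscular 151, tendon 496, blood 558 and cartilage 8.35 CPM. Without replicate 2 they were NNC 18.3%, genomic 2.19%, intergenic 0.283% and slow-fibre 2437, mitochondrially encoded 1752, mitochondrial rRNA 50.5, tendon 101, adipocyte 2285 and ribosomal 8988 CPM. Median log2 ratios of 5 lists turned, each inside the central 95% of random lists before and after: with TMM, which moves every ratio by one amount, to 0.017 (glycolysis), 0.0012 (creatine), 0.10 (coupling) and 0.049 (proteolysis), and with complete chains to -0.070 (imprinted). The share of differing genes that were higher in replicate 2 turned from 42.5% to 59.1% with TMM and 63.2% with DESeq2, both by an exact binomial test, which alone left it at 42.5%. Without single-exon transcripts the share of annotated reads was 71.4%, of genomic 0.0546%, antisense 0.0719% and intergenic 0.0284%, since nearly all reads of those classes are single-exon. Transcripts with 5 or more reads gave 69.9% annotated, and 1 class definition gave 3.98% NIC. Genes detected at 5 reads numbered 7930. The Myh4 share was 42.4% with annotated reads and 60.9% with complete chains (annotated, NIC and NNC) alone. Over annotated nuclear genes, lists moved to 109139 (filament), 49277 (glycolysis), 11052 (coupling), 2299 (imprinted) and 3965 (smooth muscle) CPM. With complete chains they moved to 115174 (filament), 43993 (glycolysis), 96967 (creatine), 6503 (coupling), 2423 (imprinted), 422 (endothelial), 3468 (smooth muscle) and 1.76 CPM (keratinocyte). Differing genes, 2311 by Fisher's test, numbered 2142 by edgeR's exact test at a dispersion of 0.0001 and 200 at 0.04. An exact binomial test gave 2311, 2263 over 8752 genes with a length and 2202 over 8423 with an annotated length, and with the length trend removed 1144 and 1143 over the same genes. Removing the trend turned the share higher in replicate 2 from 41.6% to 56.6%, and from 41.4% to 55.6% with annotated lengths. Of the 1144, 868 were among the 2311. Leaving out Atp2a1 gave 2586, of which 29.1% were higher in replicate 2. Median log2 ratios of lists that no longer stood apart were -0.25 (myosin, members with 5 reads), -0.54 (myogenic, members with 5 reads), -0.63 (myogenic, complete chains), 0.55 (embryonic, complete chains) and, against length-matched lists, -0.74 (myosin), -0.31 (filament), 0.66 (embryonic), 0.42 (leukocyte) and 0.87 (noncoding). Length matching left out members without a length, Peg3 among the embryonic and Tsix and Xist among the noncoding genes. With them the medians were 0.90 (embryonic) and 1.17 (noncoding), so matching alone did not change the standing of these lists. Those that newly stood apart with complete chains were -0.30 (glycolysis), -0.79 (dystrophin), -0.57 (fibroblast) and -0.85 (smooth muscle), and against length-matched lists -0.64 (endothelial). Genes with differing isoform shares went from 33 to 21 with annotated isoforms, 134 with ISM kept and 51 with classes per library. The Schwann cell list had too few members with complete chains for a value. Genes with several isoforms went from 800 to 442 above 20%, 350 with 50 reads and 499 with annotated isoforms. Chains found again were 73.3% (NIC) and 65.2% (NNC) at 2 reads, 99.5% and 99.3% at 10 reads, and 79.1% and 80.9% with both ends within 100 bases. Except where fewer genes, reads or chains entered, the cause was not tested. Depth limits genes under 10 reads and 2-fold differences, of which simulation recovered 34.0%.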

Other observations

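The long noncoding and nuclear RNA list, at 942 ± 177 CPM (SD, n = 2), was led by H19, and Neat1 differed most within it, with 19 reads in replicate 1 and 306 in replicate 2 (log2 ratio 3.43). Malat1 had 18 and 32 reads, and 1110002J07Rik and Snhg11 had none in either library. The mitochondrial rRNA genes were at 111 ± 86.0 CPM, with mt-Rnr2 at 39 and 190 reads and mt-Rnr1 at 15 and 78. Among excitation-contraction coupling genes Hrc (1055 and 5834 reads, log2 ratio 1.92) and Trdn (859 and 2920, 1.22) were higher in replicate 2 and Srl (4665 and 2426, -1.48) lower. Among proteolysis and atrophy regulators Gabarapl1 had 85 and 487 reads, and among fibroblast genes Col3a1 had 2851 and 1099 while Col1a2 had 232 and 623. Col1a2 was chosen after its values were seen. With the length trend removed, also chosen after seeing the data, log2 ratios were 4.02 for Neat1, 2.18 for Hrc, 0.79 for Trdn, -0.83 for Srl, 1.98 for Gabarapl1, -1.26 for Col3a1 and 1.51 for Col1a2, and all passed the adjusted exact binomial test.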
